A study of Triticum aestivum with 3 samples.

How the data were processed

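Leaf small RNA from wheat seedlings was measured after 2 days of treatment in 3 samples, 1 for each treatment: control, dithiothreitol (DTT), and DTT together with tauroursodeoxycholic acid (TUDCA). DTT is a reducing agent that disturbs disulfide bond formation in the endoplasmic reticulum. TUDCA is a bile acid used as a chemical chaperone. Each treatment has 2 RNA pools, and per the labels both pools of a treatment were made from its biological replicates. How the replicates were divided between the pools is not given in the sources used here. The 2 pools were treated as repeat runs of 1 sample. No p-value between treatments was computed, since the labels do not give the pools as independent samples.

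The values are signal, namely normalized reads that the authors deposited in 1 table with 6 columns, per the file headers. Libraries were made with a TruSeq small RNA kit and read as 50-base single ends on an Illumina HiSeq, per the labels' protocols. The aligner, the counter, the filters and the rule behind the normalization are not given in the sources used here. The table pairs each sequence with a miRNA name, a note on whether the sequence is registered in exactly that form, and, for 1688 of its 1969 rows, a precursor position on wheat scaffolds, transcripts or assembled sequences. A name carries the species it was registered from (tae wheat, ata Aegilops, osa rice, ath and aly Arabidopsis) and the changes from the registered form (L and R for the ends, ss for substitutions).

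Most values in a pool were whole multiples of 1 step. The step was taken as the most common value divided by the smallest whole number for which at least 90% of the values above 0 came out whole. With a tolerance of 0.01 reads, between 95.1% and 97.3% of the values in each pool came out whole. The steps gave about 420488 and 330652 reads for the control pools, 611784 and 752518 for the DTT pools, and 638382 and 1211765 for the DTT+TUDCA pools, counting distinct sequences in the table only. Sequences shared by several names carry fractions of a read, so no count test was run. Values worth 1 read were nearly absent (2 to 7 per pool, against 147 to 214 values worth 2 reads), so a value listed at 0 gives no upper limit.

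The 1969 rows were reduced to 1896 distinct sequences. The 1896 entries hold 1524 distinct sets of 6 values, since some neighbouring names share their reads. The design chosen before the data were examined was written for raw counts scaled to library totals, with a fallback for a table without counts, and the fallback was used. It sums the 2 pools of a treatment, keeps entries with at least 20 normalized reads over a comparison, and takes the log2 ratio of the sums plus a pseudocount of 1. The pseudocount shrinks the ratios of low entries. An entry without listed reads in a pool may have held some, which can overstate its ratio. An entry counted as higher or lower when the ratio was at least 2-fold. No interval and no test goes with this count. The authors' own scaling was thus the main one, and rescaling to equal totals took its place among the alternatives.

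The 12 miRNA lists fixed before the data were examined were matched on the family number. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 10 bins. A list was said to stand apart below the percentile 2.5 or above 97.5, as a description of these libraries. The rule for named miRNAs took the 10 highest and 10 lowest ratios of each comparison among entries past the 2-fold limit, the 5 most abundant entries, and up to 3 most abundant members of each list. The report names a part of these. Entries named outside the rule are said to have been chosen after their values were seen.

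Alternatives chosen before the data were examined were median-of-ratios scaling, trimmed mean of M values (TMM, computed here by hand from the implied reads with 30% and 5% trimming), equal totals, no floor, a floor of 100, a 95% counting interval beyond 2-fold, a 1.5-fold limit, all rows as listed, a pseudocount of 5, single pools, reads split at random, and members summed to families. Chosen after seeing the data were scaling to the grass-enriched list (median-of-ratios over its 52 entries above 0 in all 6 pools), the use of grass-named entries alone (548 entries), the requirement that the pools of 2 treatments do not overlap, the merging of identical values, and leaving out each pool in turn, with the other pool counted 2 times. Chance levels for the return, the correlation and the overlap came from 100 simulations of counting error.

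The steps were tested on simulated pools for DTT against control with 200 entries changed. In the first test the changed entries were drawn from those with at least 10 normalized reads in the summed control pools, in a run on 929 measured entries. Of the 94 entries changed 4-fold, 86.2% were called in the right direction, and of the 106 changed 8-fold, 86.8%. The entries missed were lowered ones, of which 31 of 44 (4-fold) and 44 of 58 (8-fold) were called, so the floor hides part of the low entries that fall. The draw was then raised to entries with at least 20 normalized reads in control, and the shares became 98.9% and 99.1%. Among 750 unchanged entries, 4.0% passed the 2-fold limit from counting error alone, in a run on 948 measured entries. The simulated pools differed by counting error only, while 186 of 683 entries lay 2-fold apart between the real control pools. These shares therefore do not describe the rule on the real pools. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.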

Results

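The study asked which miRNAs respond to stress of the endoplasmic reticulum in wheat leaves. Small RNA of wheat (Triticum aestivum) leaves was read in 1 sample per treatment, each as 2 pools: control, DTT, and DTT+TUDCA after 2 days. The 2 pools were treated as repeat runs of 1 sample, so each value describes these libraries. The spread between the 2 pools of a treatment was not split into plants and library preparation. The pools hold between 1173 and 1665 of the 1896 distinct sequences above 0. Sequences of 21 nt, the usual length of plant miRNAs, took 71.9% to 82.7% of the normalized reads of a pool. The miR396 family, which targets growth-regulating factors, was the most abundant family in all 6 pools, with 27.3% to 35.6%. The entry with the highest mean was ata-miR396e-5p, at 199626 and 146823 normalized reads in the control pools.

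The pools of 1 treatment differed in their makeup. The fixed list of grass-enriched miRNAs took 1.56% and 5.05% of the normalized reads in control pools 1 and 2, 1.67% and 6.33% in the DTT pools, and 13.6% and 1.08% in the DTT+TUDCA pools. The 104 sequences registered in exactly that form from Arabidopsis and without a wheat precursor position took 4.35% and 3.71% in the control pools, 5.14% and 5.52% in the DTT pools, and 2.23% and 5.97% in the DTT+TUDCA pools. Of miR168, which targets ARGONAUTE1, the form named mtr-miR168b, without a wheat position, was read at 6535 to 11150 normalized reads per pool. The rice form osa-miR168a-5p was at 50.9 to 595 (this entry was chosen after its values were seen). No entry carried a human, mouse, rat, fly or worm name, though entries named csa belong to let-7, miR-124 and other families known from animals. The reproductive-tissue list had 1 entry, ata-MIR2275a-p3, at 1.44 normalized reads in DTT pool 2 and 0 in the others. Between DTT+TUDCA pools 1 and 2, 625 of 882 entries with at least 20 normalized reads lay 2-fold apart, against 186 of 683 between the control pools and 235 of 698 between the DTT pools. Some pools of different treatments lay closer, with 85 of 653 entries 2-fold apart between DTT pool 1 and DTT+TUDCA pool 2, 142 of 648 between control pool 1 and DTT pool 1, and 154 of 617 between control pool 1 and DTT+TUDCA pool 2. Scaling to the grass-enriched list, used beside the deposited values for some entries, did not bring pools of 1 treatment closer throughout. Of the grass-named entries outside that list, those 2-fold apart went from 51 to 90 of 164 between the control pools, from 77 to 91 of 174 between the DTT pools, and from 181 to 142 of 242 between the DTT+TUDCA pools. The abundant ata-miR396e-5p, close between the DTT+TUDCA pools as deposited (107299 and 121577), was at 20554 and 363957 after this scaling.

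**Figure D1:**
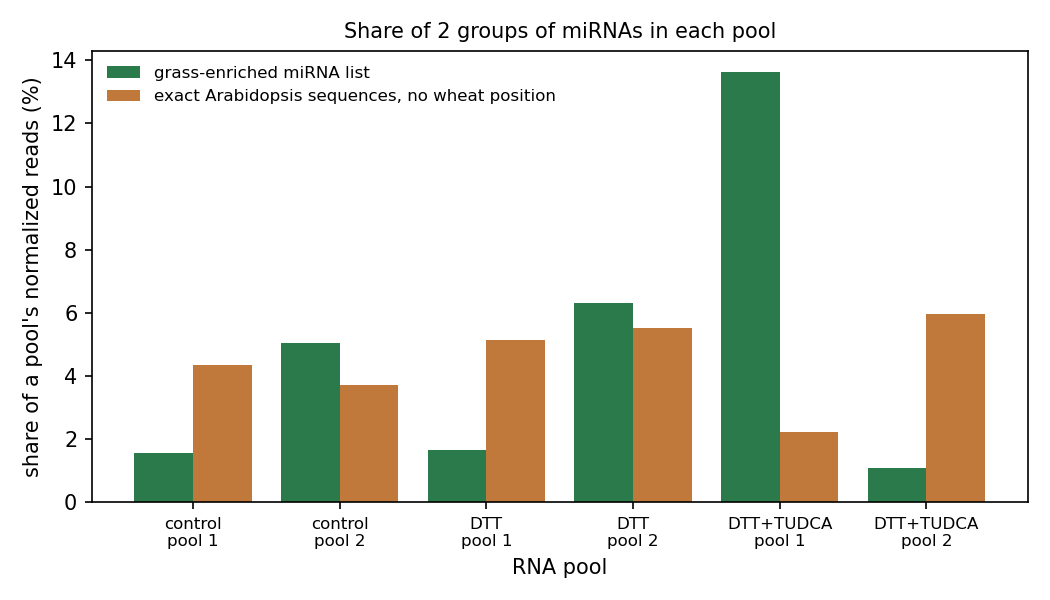
Bars give the share (%) of each pool's normalized reads in the fixed grass-enriched miRNA list and in the 104 exact Arabidopsis sequences without a wheat position, for the 6 pools, with no error bars since each pool is 1 library. The grass-enriched share runs from 1.08% in DTT+TUDCA pool 2 to 13.6% in DTT+TUDCA pool 1.

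DTT against control asks what the reducing agent alone did. Of the 6 measured miRNAs of the copper and laccase list that carry wheat or Aegilops names, 5 were at least 2-fold higher with DTT, and tae-miR408_L-1 was 1.57-fold higher. tae-miR398, a regulator of copper/zinc superoxide dismutase, was at 14.1 and 20.4 normalized reads in the control pools and at 78.4 and 148 in the DTT pools, 6.39-fold on the summed values. ata-miR528-5p, from a family found in monocots, went from 17.3 and 11.9 to 73.1 and 204, 9.22-fold. The passenger form ata-miR398f-5p_L+1R-1 was 16.97-fold higher, from 21.04 summed normalized reads. tae-MIR397-p5, of a family that regulates laccases, was 12.09-fold higher, and tae-miR397-5p, another sequence of the same precursor, 8.03-fold, from 5.09 and 3.39 summed normalized reads. Without DTT pool 2 the ratios of ata-miR528-5p, ata-miR398f-5p_L+1R-1, tae-MIR397-p5 and tae-miR397-5p were 4.89-fold, 8.67-fold, 7.71-fold and 4.03-fold. Those of tae-MIR397-p5 and tae-miR397-5p were 6.59-fold and 4.53-fold without control pool 1. Without control pool 2 they were 73.67-fold and 35.29-fold, but both entries are listed at 0 in control pool 1. These last values rest on the pseudocount of 1 and measure no ratio. tae-miR5200, which targets FT genes of flowering time in grasses, was lower, from 98.9 and 210 to 26.1 and 70.6, 3.18-fold on the summed values. It was 2.03-fold lower without control pool 2 and 5.83-fold lower without DTT pool 2. Apart from ata-miR398f-5p_L+1R-1 and tae-MIR397-p5, which the rule for DTT+TUDCA against control named, the entries given by value here were chosen after their values were seen. The grass-enriched share was 1.56% and 5.05% in the control pools and 1.67% and 6.33% in the DTT pools.

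In all, 161 entries were at least 2-fold higher and 98 lower among 958 measured, with a median log2 ratio of 0.08. The pools of the 2 treatments did not overlap for 127 of the higher and 78 of the lower entries. The balance depended on the pools, with 241 higher and 149 lower without DTT pool 1, 207 and 99 without control pool 2, 176 and 166 without DTT pool 2, and 173 and 186 without control pool 1. DTT pool 1 against control pool 2 gave 208 higher and 253 lower. With the grass-list scaling of all entries, 215 were higher and 88 lower, and with grass names alone 40 and 16 of 282. Of the 17 measured members of the copper and laccase list, 5 were higher and 0 lower. The 5 are the wheat and Aegilops entries tae-miR398, ata-miR528-5p, ata-miR398f-5p_L+1R-1, tae-miR397-5p and tae-MIR397-p5. The most abundant members of that list, osa-miR398a_1ss21TG and ath-miR398b-5p, had log2 ratios of -0.43 and -0.85, and the list's median lay at percentile 30.02 of random lists. Scaled to the grass-enriched list and with grass names alone, 6 of 11 members were higher and the median of 1.03 lay at percentile 99.9.

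Among the other lists, the grass-enriched miRNAs stood apart, with 3 members higher and 5 lower of 55 and a median log2 ratio of -0.10 (percentile 0.56). Without control pool 2 that list's median, taken relative to all entries, turned from -0.18 to 0.55, and without DTT pool 1 to 0.12. No list stood apart in this comparison with a floor of 100 or with members summed to families. The SPL and phase change list, with miR156 and miR172, had 6 higher and 4 lower of 53 (median -0.12, percentile 2.73). Scaled to the grass-enriched list and with grass names alone it stood apart, with 1 higher and 3 lower of 18 (median -0.11, percentile 2.12). Its most abundant member, ata-miR172b-3p, was at 24853 and 15397 in the control pools and 15475 and 23962 in the DTT pools. The list of other transcription-factor regulators had 19 higher and 13 lower of 152 (percentile 8.04), auxin signalling 7 and 6 of 60 (percentile 63.1), and phosphate and sulphate nutrition 0 and 3 of 17 (percentile 48.9). Silencing machinery had 0 higher and 3 lower of 24 (percentile 58.1), and the phasiRNA triggers 2 and 2 of 9 (percentile 66.1). The 2 higher phasiRNA entries, ptc-miR482a.1_L+5 and ptc-miR482c-3p, carry poplar names and were above 0 in DTT pool 1 alone. The repeat-derived miRNAs had 4 and 0 of 12 (percentile 52.8), and the predicted miRNAs 8 and 6 of 59 (percentile 57.4). Scaled to the grass-enriched list and with grass names alone, these counts were 14 and 3 of 82 for the other regulators, 4 and 4 of 36 for auxin signalling, 4 and 0 of 11 for phosphate and sulphate nutrition (percentile 95.16) and 2 and 0 of 11 for silencing machinery. They were 0 and 1 of 5 for the phasiRNA triggers and 0 and 0 of 9 for the repeat-derived miRNAs, and none of these 6 lists stood apart there.

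The 10 highest ratios by the naming rule all belonged to entries with poplar (ptc) or csa names that had nearly all of their DTT reads in 1 pool. ptc-miR472a was at 1068 normalized reads in DTT pool 1 and 4.32 in pool 2, against 4.71 and 0 in the control pools. ptc-miR1448_L+1R+1 was at 540 and 1.44 and listed at 0 in both control pools. csa-let-7d_R-4_1ss10TA was listed at 0 in DTT pool 1 and at 196 in pool 2, and csa-miR-124_L+1R-5 at 0 and 98.6, both listed at 0 in control. At the low end, ata-miR169h-3p_L-1 was at 18.8 and 30.6 in control and at 3.13 and listed 0 with DTT. aly-miR169n-3p was at 12.6 and 33.9 and then listed at 0 in both DTT pools, and aly-miR393b-3p_L-3 at 12.6 and 15.3 and then at 0 listed and 2.16. The predicted PC-3p-125407_17 was at 14.1 and 8.49 and then listed at 0 in both. Of the abundant entries, aly-miR158a-3p, from a family known from the crucifers, had a log2 ratio of -0.49 with pools that did not overlap. ata-miR396e-5p was at -0.27, aof-miR159 at -0.08, ata-miR396c-5p at 0.37 and ata-miR167a-5p at 0.45, all with overlapping pools.

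**Figure D2:**
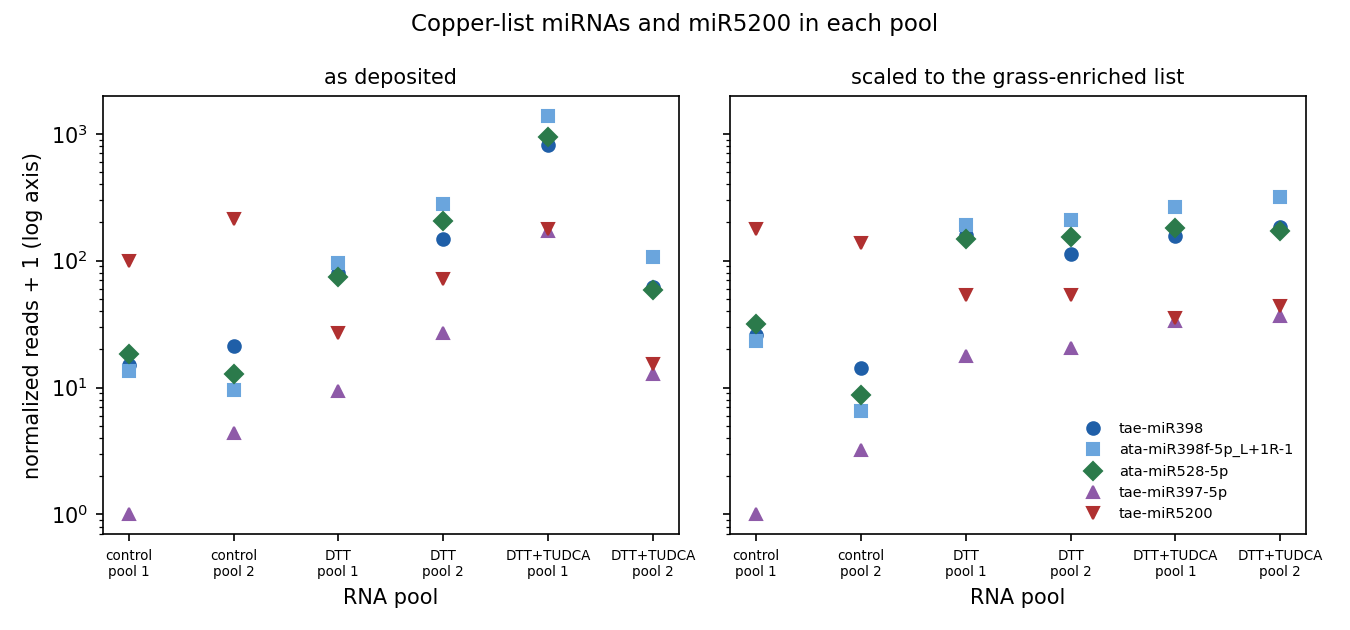
Points give normalized reads plus 1 (log axis) in each of the 6 pools for tae-miR398, ata-miR398f-5p_L+1R-1, ata-miR528-5p, tae-miR397-5p and tae-miR5200, as deposited on the left and scaled to the grass-enriched list on the right; there are no error bars since each pool is 1 library. On the right, tae-miR398 sits at 25.2 and 13.2 in control, 157 and 111 with DTT, and 156 and 182 with DTT+TUDCA, while tae-miR5200 sits at 176 and 137, 52.4 and 53.1, and 34.1 and 43.2.

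The mature tae-miR398 (TGTGTTCTCAGGTCGCCCCCG, 21 nt) has its precursor on the plus strand of TGACv1 scaffold 220641, of chromosome 3B, from 245824 to 245943. tae-miR397-5p (TCACCGGCGCTGCACACAATG) and tae-MIR397-p5 (TTGAGTGCAGCGTTGATGAAC) lie in 1 precursor on scaffold 486753 of 6AS, plus strand, 26213 to 26305. tae-miR5200 (TGTAGATACTCCCTAAGGCTT) lies on scaffold 592091 of 7BS, minus strand, 110211 to 110303. Gene annotation around these precursors was not used here.

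DTT+TUDCA against DTT asks whether the chaperone changed the response. tae-miR9772 and tae-miR9674b-5p of the grass-enriched list and osa-miR827 of the phosphate list were higher in the summed DTT+TUDCA pools, by values that came from pool 1. tae-miR9772 was at 10494 normalized reads in DTT+TUDCA pool 1 and 839 in pool 2, against 1135 and 2418 with DTT. tae-miR9674b-5p was at 22002 and 1886, against 3590 and 6810. osa-miR827, from a family that targets SPX-domain genes of phosphate balance, was at 6626 and 413, against 736 and 1727. Their log2 ratios of 1.67, 1.20 and 1.51 were 0.14, -0.32 and -0.15 after scaling to the grass-enriched list, which holds the first pair. ata-miR396e-5p, the most abundant grass-named entry, had a deposited ratio of -0.33, with pools that did not overlap. The grass-enriched share was 13.6% and 1.08% in these 2 pools. The copper entries tae-miR398 and ata-miR528-5p were 3.85-fold and 3.58-fold higher than with DTT as deposited, and 1.26-fold and 1.17-fold higher after scaling to the grass-enriched list. Without DTT+TUDCA pool 1 their deposited log2 ratios turned to -0.89 and -1.27.

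In all, 442 entries were higher and 38 lower of 1099, with a median log2 ratio of 0.72, and the pools did not overlap for 83 and 20. Without DTT+TUDCA pool 1, 52 were higher and 212 lower, and without pool 2, 711 and 127. With the grass-list scaling of all entries, 128 were higher and 57 lower. With the grass-list scaling and grass names alone, 30 were higher and 6 lower of 304. Lists above random lists were the repeat-derived miRNAs (31 of 31 higher, percentile 100), the grass-enriched miRNAs (62 of 70 higher, 0 lower, percentile 100), the copper and laccase list (12 of 22 higher, 0 lower, percentile 99.9) and the predicted miRNAs (52 higher and 3 lower of 83, percentile 99.7). The repeat-derived, grass-enriched and predicted medians, relative to all entries, turned to -1.28, -1.20 and -1.20 without DTT+TUDCA pool 1. Lists below were the other transcription-factor regulators (57 higher and 5 lower, percentile 1.84) and the phasiRNA triggers (3 higher and 2 lower of 9, percentile 1.25), and these medians turned to 0.21 and 0.007 without the same pool. The 2 lower phasiRNA entries were the poplar-named ptc-miR482a.1_L+5 and ptc-miR482c-3p, above 0 in DTT pool 1 alone, at 90.9 and 63.7 normalized reads. With the grass-list scaling and grass names alone, the copper and laccase list stayed above, with 3 higher and 1 lower of 13 (percentile 98.32). Among its members, osa-miR397a was 6.56-fold lower, at 2.04 and 0 listed against 16.77 and 2.17 with DTT. The repeat-derived list, the other regulators and the phasiRNA triggers no longer stood apart there (percentiles 74.89, 77.57 and 55.36). Auxin signalling (16 higher and 2 lower of 59, percentile 3.21), silencing machinery (5 and 0 of 23, percentile 8.28), SPL and phase change (18 and 0 of 57, percentile 10.3) and phosphate and sulphate nutrition (7 and 1 of 18, percentile 55.5) did not stand apart.

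Among the 10 highest ratios, zma-MIR164h-p5_2ss4CG17CG_1 was at 78.8 and 38.7 with DTT+TUDCA, against 0 listed and 7.20 with DTT. ata-miR5168-5p was at 99.1 and 6.19 against 3.13 and 2.16, and the predicted PC-5p-73958_33 at 79.9 and 6.70 against 0 listed and 2.88. The 10 lowest were poplar and csa entries with nearly all of their DTT reads in 1 pool, such as ptc-miR472a, at 0 listed and 2.06 with DTT+TUDCA. ath-miR173-5p, which starts TAS siRNA production in Arabidopsis, was at 1658 and 7403 against 7718 and 8610 with DTT and 5511 and 2361 in control (chosen after its values were seen). Its log2 ratio to DTT was -0.85, under the 2-fold limit, and 0.03 after scaling to the grass-enriched list. That scaling put its DTT+TUDCA pools at 318 and 22163, so the 0.03 comes mostly from pool 2. DTT against control gave 2.07-fold, with pools that did not overlap, 1.94-fold after that scaling, and 1.48-fold and 3.46-fold without control pool 2 or 1.

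DTT+TUDCA against control shows the combined treatment. The wheat and Aegilops entries of the copper and laccase list were higher in both DTT+TUDCA pools than in both control pools, except tae-MIR398-p5, at 29.8 and 1.03 against 0 listed and 3.39 (chosen after its values were seen). tae-miR398 was at 812 and 60.8 against 14.1 and 20.4, 24.6-fold on the sums, and 8.60-fold after scaling to the grass-enriched list. ata-miR398f-5p_L+1R-1, at 1369 and 105 against 12.6 and 8.49, was 66.9-fold higher as deposited and 20.03-fold after scaling. ata-miR528-5p, at 935 and 57.2 against 17.3 and 11.9, was 32.96-fold and 8.91-fold higher. These sums came mostly from DTT+TUDCA pool 1, and without it the deposited ratios were 3.46-fold for tae-miR398, 9.59-fold for ata-miR398f-5p_L+1R-1 and 3.83-fold for ata-miR528-5p. tae-miR408_L-1, whose family targets plantacyanins, was at 940 and 258 against 115 and 193, 3.88-fold on the sums and 1.67-fold without DTT+TUDCA pool 1. The more abundant aof-miR408_L+1R-1 was 1.03-fold higher. The most abundant of the list, osa-miR398a_1ss21TG and ath-miR398b-5p, had log2 ratios of -0.155 and -0.522. tae-miR5200 was at 178 and 14.4 against 98.9 and 210, 1.60-fold lower as deposited and 4.0-fold lower after scaling, and its deposited log2 ratio turned to 0.20 without DTT+TUDCA pool 2. The grass-enriched share was 13.6% and 1.08% against 1.56% and 5.05%.

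In all, 458 entries were higher and 67 lower of 1107, with a median log2 ratio of 0.66, and the pools did not overlap for 151 and 58. That median was 0.44 with median-of-ratios, 0.47 with TMM and 0.49 with the grass-list scaling, under which 275 entries were higher and 89 lower. Without DTT+TUDCA pool 1, 139 were higher and 221 lower, and without pool 2, 651 and 109. With the grass-list scaling and grass names alone, 61 were higher and 16 lower of 290. The repeat-derived list (30 of 31 higher, percentile 100), the grass-enriched list (54 of 70 higher, percentile 100), the predicted miRNAs (54 higher and 3 lower of 81, percentile 99.8) and the copper and laccase list (12 of 22 higher, percentile 99.4) lay above random lists. Relative to all entries, the first 3 medians turned to -0.71, -1.60 and -0.87 without DTT+TUDCA pool 1, and the copper median turned to -0.10 with a floor of 100. The copper median was 0.05 without DTT+TUDCA pool 2 and 1.72 without control pool 2. Silencing machinery (3 higher and 1 lower of 24, percentile 0.54), the other transcription-factor regulators (51 and 9 of 165, percentile 1.26) and SPL and phase change (14 and 1 of 57, percentile 1.99) lay below. The medians of the first pair turned to 0.19 and 0.09 without DTT+TUDCA pool 1, and to 0.03 and 0.08 with the grass-list scaling and grass names alone. In that setting the copper and laccase list stayed above, with 8 of 11 higher, and the repeat-derived and SPL lists no longer stood apart (percentiles 76.02 and 21.45). Auxin signalling (14 and 5 of 58, percentile 12.4), phosphate and sulphate nutrition (8 and 2 of 18, percentile 47.0) and the phasiRNA triggers (2 and 1 of 7, percentile 13.5) did not stand apart.

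By the naming rule, gma-miR4995_R+1 was at 295 and 17.5 with DTT+TUDCA, against 0 listed and 3.39 in control. The predicted PC-3p-5163_420 was at 926 and 74.8 against 9.42 and 5.09, and tae-MIR408-p5_1ss20GA at 60.7 and 5.67 against 0 listed in both control pools. Lower were ath-miR826a, at 0 listed and 5.16 against 28.3 and 16.97, and aly-miR395e-5p_R-1, listed at 0 against 15.7 and 8.49. The predicted PC-3p-491_4542, the most abundant of its list, was at 557 and 387 against 1563 and 1246, with log2 ratios of -1.14 for DTT and -1.57 for DTT+TUDCA, and pools that did not overlap in either comparison. The DTT ratio was -0.97 without control pool 1 and -0.85 without DTT pool 1.

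The return toward control asks whether TUDCA brought the DTT changes back. Of the 259 entries 2-fold apart in DTT against control, 79 (30.5%) lay nearer to control with DTT+TUDCA. With DTT+TUDCA reads redrawn from the DTT levels, counting error gave a median of 2 and at most 8 in 100 simulations. These simulations kept the control and DTT values that chose the entries, so they leave out counting error in that choice. With 1 DTT pool put in place of DTT+TUDCA and the other kept as DTT, 172 of 342 (50.3%) and 216 of 390 (55.4%) lay nearer to control. The matching values for DTT+TUDCA, with entries chosen on the same single DTT pool, were 166 of 342 (48.5%) and 143 of 390 (36.7%). The number was 138 of 359 without control pool 1 and 58 of 306 (19.0%) without control pool 2, and 93 and 118 of 259 without DTT+TUDCA pool 1 or 2. Of the 56 grass-named entries that were 2-fold apart after the grass-list scaling, 12 (21.4%) lay nearer to control, and the copper entries tae-miR398, ata-miR528-5p and tae-miR397-5p were not among them.

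Across 921 entries measured in both, the log2 ratios of DTT and of DTT+TUDCA against control correlated (Pearson's r 0.75, Spearman's rho 0.66, covariance 1.08). Entries are not independent replicates, and both ratios share the control pools. Unchanged pools against a shared control gave 0.69, 0.64 and a covariance of 0.11 in simulation. With control pool 1 for DTT and pool 2 for DTT+TUDCA, r was 0.60 (covariance 1.06), and with the pools exchanged it was 0.14 (covariance 0.33). Without DTT pool 2 it was 0.46. Both treatments were higher than control for 117 entries and lower for 38, where independent lists of those sizes would share 49.7 and 5.6. Unchanged pools against a shared control, drawn with counting error alone, shared a median of 5 higher and 4 lower, and at most 17 and 9. With control pool 1 for DTT and pool 2 for DTT+TUDCA, 132 were higher and 23 lower in both, where independent lists would share 63.7 and 4.4. With the control pools exchanged, 76 and 15 were shared, against 65.7 and 9.4. The higher entries include tae-miR398, ata-miR528-5p and tae-miR397-5p. Part of the excess may come from the shared control pools.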

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

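The scaling to the grass-enriched list, the use of grass names alone, the requirement that pools do not overlap, the merging of identical values, the use of 1 pool of a shared treatment for each comparison and leaving out each pool were chosen after seeing the data, and the other alternatives before. No paired analysis by pool number was run, because each treatment was taken as 1 sample and no test was run. Where a value moved or turned, the cause was not tested, unless fewer entries, fewer pools or a wider limit account for it by construction. The floors at 20 normalized reads hide low entries, and the control pools, with the fewest implied reads, limit the low end of both comparisons with control.

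The number of entries 2-fold apart was 259 for DTT against control, 480 for DTT+TUDCA against DTT and 525 for DTT+TUDCA against control. In that order it was 789, 935 and 1040 with no floor, 89, 210 and 227 with a floor of 100, and 66, 240 and 230 where the 95% counting interval had to lie beyond 2-fold. With grass-list scaling and grass names only it was 56, 36 and 77, and 32, 17 and 31 when the pools also did not overlap. A 1.5-fold limit gave 464 for DTT against control. TMM gave 276 and grass-list scaling 185 for DTT+TUDCA against DTT. Pools not overlapping left 103 for DTT+TUDCA against DTT and 209 for DTT+TUDCA against control. Single pools gave at most 461, 822 and 803, and at least 157 and 260 in the last 2 comparisons. Leaving out 1 pool at a time gave 306 to 390, 264 to 838 and 360 to 760. The lowest values of the last 2 came without DTT+TUDCA pool 1 and the highest without DTT+TUDCA pool 2, and 390 came without DTT pool 1. Median-of-ratios, equal totals, every name as listed, a pseudocount of 5 and merged identical values stayed within 1.5 times the number in each comparison.

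The number of lists standing apart was 1, 6 and 7. It was 0, 2 and 4 with a floor of 100, 0, 3 and 3 with members summed to families, and 2, 2 and 2 with grass-list scaling and grass names only. In the last 2 comparisons 1 of those 2 is the grass-enriched list, whose median this scaling holds near 0 (-0.008 and 0.002), so its place there restates the scaling and says nothing about the list. Leaving out 1 pool gave 2 to 6, 4 to 7 and 3 to 6. Of 263 list values under an alternative, 191 kept their side of the limit, 35 no longer stood apart, 17 newly did and 20 turned. Only lists that stood apart were counted as turned, so a list inside the limit could change direction among the 191. Relative to the median of all entries, the following log2 medians of lists that stood apart turned. For DTT against control, the grass-enriched list ran from -0.98 without DTT pool 2 to 0.55 without control pool 2. For DTT+TUDCA against DTT, leaving out 1 pool gave -1.56 to 0.081 for the phasiRNA triggers, -0.95 to 0.21 for the other transcription-factor regulators, -1.28 to 4.03 for the repeat-derived list, -1.20 to 1.68 for the grass-enriched list and -1.20 to 1.31 for the predicted miRNAs. The phasiRNA triggers were at 0.028 with members summed to families. With grass-list scaling and grass names only, the other transcription-factor regulators were at 0.027 and the grass-enriched list, held there by the scaling, at -0.153. For DTT+TUDCA against control, the ranges were -0.98 to 0.091 for the other transcription-factor regulators, -1.50 to 0.19 for silencing machinery, -0.71 to 3.82 for the repeat-derived list, -1.60 to 1.76 for the grass-enriched list and -0.87 to 1.43 for the predicted miRNAs. With grass-list scaling and grass names only, the other transcription-factor regulators were at 0.084, silencing machinery at 0.032 and the grass-enriched list, held there by the scaling, at -0.331. The copper and laccase list was at -0.104 with a floor of 100. Leaving out 1 pool gave 0.052 without DTT+TUDCA pool 2 to 1.721 without control pool 2.

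Single entries were rerun for part of those whose values the text gives. Of 936 values for 104 log2 ratios, 474 stayed within the counting interval, 442 moved beyond it in the same direction or from a ratio under 2-fold, and 20 turned, in 16 ratios. No 2-fold ratio of DTT against control turned. For DTT+TUDCA against DTT, leaving out 1 pool gave -1.46 to 2.08 for tae-miR9674b-5p, -1.08 to 2.56 for tae-miR9772, -1.57 to 2.43 for osa-miR827, -0.82 to 2.95 for ata-miR398f-5p_L+1R-1, -1.27 to 2.75 for ata-miR528-5p and -0.89 to 2.84 for tae-miR398. It gave -0.97 to 2.56 for osa-miR168a-5p, -0.70 to 3.34 for tae-MIR397-p5, -2.08 to 2.503 for gma-miR4995_R+1, -0.51 to 3.36 for tae-miR397-5p and -7.62 to 1.65 for csa-let-7d_R-4_1ss10TA. The lowest value came without DTT+TUDCA pool 1 in each of these 11 ratios, and csa-let-7d_R-4_1ss10TA turned without DTT pool 2, the pool that holds its reads. With grass-list scaling, tae-miR9674b-5p was at -0.322, osa-miR827 at -0.147 and gma-miR4995_R+1 at -0.434. For DTT+TUDCA against control, the ranges were -1.33 to 2.21 for tae-miR9674b-5p, -0.87 to 2.77 for tae-miR9772, -1.67 to 2.53 for osa-miR827, -0.94 to 2.60 for osa-miR168a-5p and -0.50 to 3.40 for ata-miR5168-5p, lowest without DTT+TUDCA pool 1. tae-miR9674b-5p was at -0.022 with grass-list scaling.

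The number of entries nearer to control with DTT+TUDCA was 79. It was 20 with a floor of 100, 166 with a 1.5-fold limit, 12 with grass-list scaling and grass names only, and 140 with DTT pool 2 against control and pool 1 against DTT+TUDCA. Leaving out 1 pool gave 58 without control pool 2 to 166 without DTT pool 2. The correlation of 0.754 was 0.582 with control reads split at random, 0.864 with grass-list scaling and grass names only, and 0.600 and 0.143 with 1 control pool for each comparison. With grass-list scaling, grass names only and 1 control pool for each comparison it was 0.340 and 0.388. Leaving out 1 pool gave 0.462 without DTT pool 2 to 0.866 without control pool 2. Without the miR396 family, the share of 21-nt sequences was 70.68% and 65.25% in the control pools, 73.68% and 65.43% in the DTT pools, and 61.55% and 76.40% in the DTT+TUDCA pools. With every name as listed it was 76.59% in control pool 2, 83.59% and 77.20% in the DTT pools, and 71.73% and 83.63% in the DTT+TUDCA pools.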

Other observations

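All tests of explanations in this part were chosen after the results were seen, and so were the entries named in it. Some entries had most of their reads in 1 pool. Of the poplar-named entries, ptc-miR1446a_R+1 was at 215 normalized reads in DTT pool 1, ptc-miR482a.1_L+5 at 90.9 and ptc-miR1450_R-1 at 79.4, and each was listed at 0 in the other 5 pools. ptc-miR472a and ptc-miR482a.1_L+5 belong to families that target NBS-LRR resistance genes. Poplar-named entries held 0.459% of the normalized reads in DTT pool 1 and 0.1001% to 0.125% in the others. In DTT pool 2, csa-miR-124_R-3_1ss19CA was at 1045, against 18.8 to 104 in the other pools, and csa-let-7b_R-4_1ss15AG at 74.2, against 0 listed to 2.13. let-7 and miR-124 are known from animals. The csa-named entries held 0.295% in DTT pool 2 and 0.0105% to 0.0484% in the others.

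Apart from the copper entries, other grass-named entries differed between DTT and control by more than 2-fold after scaling to the grass-enriched list, with pools that did not overlap. bdi-miR159a-5p_R+1, the passenger form of a family that targets GAMYB transcription factors, was 8.77-fold higher, at 8.39 and 7.71 in control and 96.4 and 52.6 with DTT. The mature form bdi-miR159a-3p_L-1R+1 was 3.45-fold higher, at 61.5 and 30.8 against 189 and 132. Other miR159 entries did not rise as far. The abundant aof-miR159 had a log2 ratio of 0.083 after this scaling. As deposited, the wheat entries tae-miR159a_R-1 and tae-MIR159a-p5 were at -0.316 and 0.413. tae-miR9653b_R+1 was at 5.59 and 2.20 against 23.1 and 21.7, 5.20-fold. On the lower side, osa-miR393a_L-2R+1, of a family that targets TIR1 and AFB auxin receptors, was at 565 and 176 against 126 and 86.1, 3.48-fold.

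The 2 DTT+TUDCA pools stood far apart, and a different share of reads from another plant in each may be part of the cause. If that share moved grass-named entries by 1 factor, scaling to the grass-enriched list would bring most of those 2-fold apart within 2-fold. In none of 3 tests did the number fall that far. Scaling to the grass-enriched list changed the number of other grass-named entries 2-fold apart from 181 to 142 of 242 (0.785 of the number before). In families with no exact Arabidopsis entry it went from 100 to 63 of 121 (0.63). Of those left, 26 and 21 were lower in pool 2, and only these speak against 1 factor. The other 116 and 42 were higher in pool 2, where the scaling lifts sequences that another plant shares. These counts therefore do not decide, and reads from another plant stay open. In the repeat-derived list the number went from 28 to 18 of 28 (0.643). Simulations of 1 common factor with counting error gave a median of 3 and at most 7, below the 18. This does not decide either, since the median in pool 2 was 1.03 normalized reads. The simulations also did not model the near absence of values worth 1 read. A difference in depth falls short, since 67.9% of the 53 grass-named entries with at least 1000 normalized reads, 36 in number, were 2-fold apart. Both pools carry the same treatment, so no biological explanation was tested, and a difference in library preparation or in the plants of each pool stays open.

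Exact miRNA sequences registered from Arabidopsis were abundant in these wheat libraries. For naming by similarity to wheat sequences, exact Arabidopsis entries without a wheat position were to hold under 0.1% of a pool. That limit was set after the shares were seen. The 104 such entries held 2.233% to 5.97% of a pool, above the limit. This does not decide the question, since wheat loci missing from the positions would allow any share. The 104 leave out aly-miR158a-3p, an exact sequence with a position in the table, at 21844 to 45663 normalized reads per pool. Positions are also given for csa-let-7d_R-4_1ss10TA and csa-miR-124_L+1R-5, so a position does not settle that a sequence is from wheat. Reads from another plant may be the source of the exact Arabidopsis sequences. The miR168 entries without a wheat position exceeded the grass-named ones with one by 7.74-fold to 103.2-fold over the 6 pools, and the exact Arabidopsis entries and the grass-enriched list moved in opposite directions between the DTT+TUDCA pools and between the control pools, while both rose from DTT pool 1 to pool 2, from 5.135% to 5.523% and from 1.667% to 6.326%. Wheat loci missing from the positions in the table stay open, and no biological explanation was tested.

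Members of the copper and laccase list with wheat or Aegilops names, a subset chosen after the values were seen, were higher with DTT and with DTT+TUDCA than in control. A changed share of reads from another plant is argued against, since their median log2 ratio of DTT against control was 3.236 after scaling to the grass-enriched list, with 6 of 6 members 2-fold higher, and 3.105 as deposited, with 5 of 6. Of these members, tae-miR408_L-1 was 2.05-fold higher after scaling, with pools that overlapped. tae-MIR397-p5 and tae-miR397-5p come from the same precursor, so the members are not independent. A fall of the scaling list itself is argued against by the deposited median, which does not use it (scaled to 6 repeat-derived entries of few reads the median was 3.204), and counting error by a lower 95% bound of 1.805 on the log2 ratio of 2.019 summed over all 10 such members, the low ones included. Over the whole list, only 5 of 17 measured members were higher with DTT, and its median lay at percentile 30.02 of random lists. With DTT+TUDCA against control, 12 of 22 were higher and the median lay at percentile 99.4. The most abundant members did not follow. osa-miR398a_1ss21TG was at -0.43 with DTT and -0.155 with DTT+TUDCA, ath-miR398b-5p at -0.85 and -0.522, and aof-miR408_L+1R-1 at 0.04 with each. That DTT raises the wheat and Aegilops forms is a hypothesis that no test here decides, since with 1 sample per treatment a difference in plants, handling or library stays open and could give the same values.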
